A study of Homo sapiens with 18 samples.

How the data were processed

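Bulk RNA sequencing libraries of primary human CD4+ T cells were analysed from the values that the authors deposited, without the reads. Per the labels' protocols, naive CD4+ T cells were isolated from blood mononuclear cells and activated with plate-bound anti-CD3 and anti-CD28. Lentivirus carrying a hairpin against LACC1 or an empty vector was added 24 h later, followed by 48 h of polarisation and 4 days of expansion. The Th0 medium held 5 ng/mL interleukin-2, and the iTreg medium held the same with TGF-β at 0 to 5 ng/mL, with no dose given per library. Per the labels, cDNA was primed with both oligo-dT and random hexamers, amplified, tagmented with a Nextera XT kit, which does not mark strand, and sequenced as paired reads of 50 bp.

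The count table holds whole-number read counts per Ensembl gene, not normalised, as the authors deposited it. The deposited TPM table (transcript values scaled to the same total in each library) covers the same 18 libraries, and dividing a count by its TPM gives 1 fixed gene length per gene up to a factor for the library. The deposited metadata holds a further value per library, a removal mark of 0 or 1 that the authors set for 1 library in each group and whose meaning is not stated. The submitters' processing notes name fastp 0.23.3, STAR 2.7.10b, SAMtools 1.17, deepTools 3.5.1 and the build hg19, with no role or order. The counting tool, the annotation, the use of strand and the treatment of reads that map to several places are not given in the sources used here. Genes that share exons or have near-identical copies are therefore uncertain. The reference used here was of another build (GRCh38 with GENCODE v29), so it served for gene names, transcript GC content and exon overlap, and no coordinates are printed.

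Libraries were grouped by cell type and vector as the labels give them, and replicate numbers are the donor numbers of the labels, which run from 1 to 5. Of 57269 gene IDs, 51466 matched a symbol, and these held 99.4% of counts. Before any test, 553 sex-linked IDs were left out. Total counts ranged from 5216530 to 7929314 per library. A gene with 0 counts in a group was set against a floor of 3 counts over the group, or over the library for a single library. Floors cover counting error only, and PCR duplicates are not independent molecules. The 95% intervals of LACC1 came from the edgeR fit and include the spread between replicates. No pair of libraries agreed within sampling noise (lowest chi-square per degree of freedom 9.31), so each counted as 1 sample.

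The main test was edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling, filterByExpr by group) in R 4.3.3 on the counts of all 18 libraries in 1 fit with a coefficient per group, which left 12629 genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. The comparisons were KD against EV in Th0 and in iTreg, iTreg EV against Th0 EV, and the difference of the 2 KD effects. LACC1 was also tested by a two-sided exact permutation test, and the correlation of the KD effects by exact permutation of the iTreg labels.

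The 34 gene lists cover T cell states (regulatory T cell, Th1, Th2, Th17, cytotoxic, naive and memory, early activation, coinhibitory), responses (TGF-β, NF-κB, interferon), metabolism (oxidative phosphorylation, mitochondrially encoded genes, glycolysis, tricarboxylic acid cycle, fatty acid oxidation, sterol and fatty acid synthesis, purines, arginine and polyamines), stress and growth (ATF4, unfolded protein response, NRF2, p53, proliferation, autophagy and lysosome), cell identity (CD4, CD8, B, NK, monocyte and dendritic, erythroid and platelet) and RNA quality (histones, ribosomal proteins, nuclear and stress RNAs). Of 780 members, 774 matched an ID. Some genes stand in more than 1 list. Lists with at least 3 tested members, 31 in number, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists, and also with an estimated correlation and with fry, which tests whether the members move on balance one way without comparing them with other genes. With an estimated correlation, the TGF-β list alone kept its call between iTreg EV and Th0 EV, and neither KD comparison kept one. The lowest fry adjusted p was 5.06e-06 for iTreg EV against Th0 EV, 0.770 for KD in Th0 and 0.977 for KD in iTreg.

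Named genes followed a rule. LACC1 was always named. Per comparison, the rule took the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those that passed, with a mean of at least 50 counts and the same sign in every donor pair. Per list it took up to 4 members that passed or, where none did, the 2 most abundant. Named outside the rule, after their values were seen, were FOXP3, MX1, LDLRAD4, SMURF2, SMAD3, CST7, GZMA, GZMB, NKG7, CST3, the genes described for the marked libraries, the few genes that passed only under an alternative and those of the closing observations. Of the genes that the rule takes, 1 is left out of the text because its result is withheld. The groups, tests, lists, naming rule and other settings to try were fixed before the data were examined.

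The same donor number in 2 groups marks the same donor per the labels, so the numbers pair the libraries. As a check, deviations from the group means correlated within the 5 Th0 pairs of EV and KD at 0.372 to 0.907, and within the 4 iTreg pairs at 0.591, 0.287, -0.601 and -0.367, where each of the last 2 pairs held 1 marked library. For iTreg EV and Th0 EV the 4 pairs gave -0.259, 0.509, 0.365 and 0.217, the first with 1 marked library. Pairs of unmarked libraries gave 0.0729 to 0.384 when only unmarked libraries were used. The donor block was an alternative and is given beside a result where it changed the call or moved a count by over 1.5 times. The iTreg groups held no donor 5, so with the block the donor term takes up the mark of the Th0 libraries of donor 5. The marked iTreg libraries then stand against unmarked Th0 libraries of the same donor, which partly mixes the mark with cell type. For iTreg EV against Th0 EV the interferon list median was 2.26 with the block and 1.61 with block and mark.

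The other settings were relative log expression (RLE) scaling, DESeq2 1.42.0, no low-count filter, a stricter filter (CPM of at least 1 in at least 4 libraries), only the groups compared, the donor as a replicate block, limma on log2(TPM + 1) and log2(TPM + 0.1), TPM without a filter, and each library left out in turn. Added after the data were seen were fits without the 4 marked libraries, with the mark as a covariate, each of these with the donor block, and with the GC trend of each library removed (smoothing span 0.3; 98.1% of tested genes had a GC value). The marked libraries raised the spread between replicates, with an edgeR biological coefficient of variation of 0.854 in the main model and 0.452 with the mark as a covariate.

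The code was tested on simulated counts with 200 of 12629 genes changed. The changed genes were drawn from those with a simulated mean of at least 50 counts. The simulated counts held no donor effect and were fitted with the model that made them. The shares below cover neither lower genes nor a smaller number of changed genes. In the main edgeR model 25% of 4-fold and 1% of 2-fold changes were called for KD in Th0, 11% and 0% for KD in iTreg, and 23% and 1% for iTreg EV against Th0 EV. With the mark as a covariate the shares were 95% and 33%, 79% and 20%, and 80% and 24%. In the main model DESeq2 called 59%, 36% and 49% of the 4-fold changes in these comparisons. It also made 34, 30 and 19 false calls, of genes left unchanged, against 0, 2 and 2 with edgeR. DESeq2 counts are therefore less certain. Python 3.11.15 and matplotlib 3.10.9 were used for the remaining steps and the figures.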

Results

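Gene expression was measured by bulk RNA sequencing in primary human CD4+ T cells that carried either a short hairpin RNA against LACC1, which encodes a laccase-domain enzyme of purine nucleoside metabolism, or an empty lentiviral vector (EV). Naive CD4+ T cells from blood were activated through CD3 and CD28 and received virus 24 h later. The cells were grown either as activated, non-polarised cells (Th0) or under conditions that induce regulatory T cells (iTreg), for which TGF-β was added to interleukin-2. The labels gave the TGF-β of the iTreg medium only as a range from 0 to 5 ng/mL, so the dose behind each iTreg library was not known. The 18 libraries came from up to 5 donors per group and fell into 4 groups, with 5 Th0 EV, 5 Th0 knockdown (KD), 4 iTreg EV and 4 iTreg KD libraries. Total counts ranged from 5771804 to 7929314 in Th0 EV, from 5431906 to 6770702 in Th0 KD, from 5514938 to 6693386 in iTreg EV and from 5216530 to 6292493 in iTreg KD.

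In each of the 4 groups, 1 library carried a removal mark in the deposited metadata, whose reason was not stated. The 4 marked libraries stood apart from the 14 others along the first principal component, which held 53.9% of the variance. IL2RA, the interleukin-2 receptor α chain, was measured at a mean of 823 CPM in the marked and 40.1 CPM in the unmarked libraries, and CD3E, a chain of the T cell receptor complex, at 229 and 13.7 CPM. CD4, the coreceptor that defines these cells, was at 415 and 40.8 CPM, whereas FOXP3, the lineage factor of regulatory T cells, was at 26.8 and 31.0 CPM. Ribosomal protein genes took 2.07% to 3.08% of counts in the marked libraries and 0.630% to 1.13% in the unmarked ones, and mitochondrially encoded genes took 5.69% to 10.9% and 0.931% to 5.63%. ACTB, encoding β-actin, took 3.21% to 3.55% of counts in the marked libraries against 5.34% to 8.63% in the others. Between 17055 and 18400 genes were detected in a marked library and between 14191 and 15753 in an unmarked one.

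**Figure D1:**
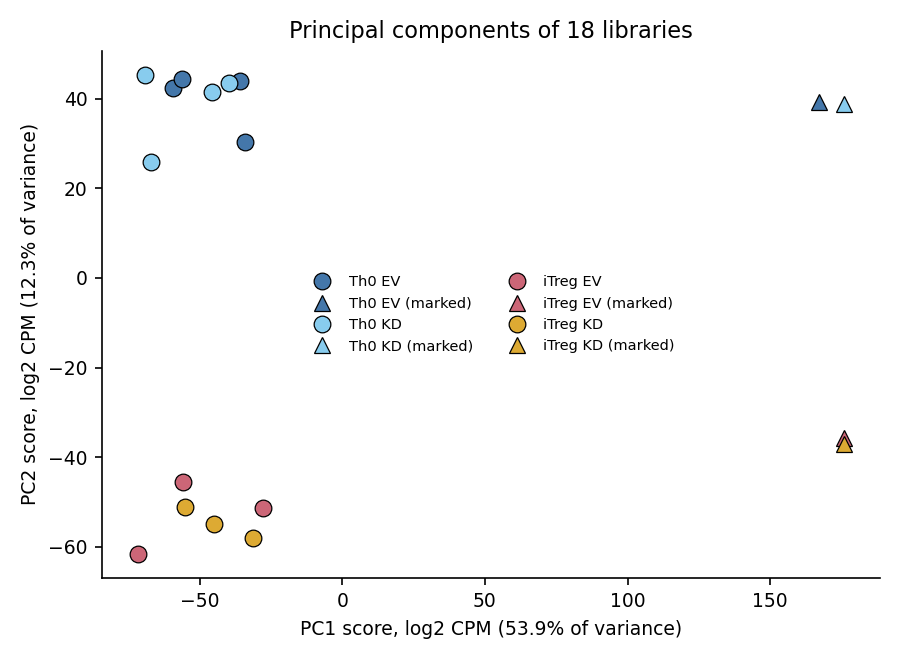
Principal components 1 and 2 of log2 CPM for the 18 libraries, with the share of variance of each component on its axis (53.9% and 12.3%). Colours give the 4 groups and triangles the 4 marked libraries, which lie apart on component 1.

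LACC1 (ENSG00000179630.6), the gene targeted by the hairpin, was measured at low levels in every group. In Th0 it was at 3.66 ± 2.60 CPM (SD, n = 5) in the libraries labelled EV and at 2.59 ± 2.39 CPM (n = 5) in the libraries labelled KD. In iTreg it was at 9.28 ± 6.37 CPM (n = 4) in the libraries labelled EV and at 5.85 ± 3.34 CPM (n = 4) in the libraries labelled KD. LACC1 counts for Th0 replicates 1 to 5 were 15, 25, 62, 10 and 14 in EV and 0, 28, 17, 35 and 2 in KD. For iTreg replicates 1 to 4 they were 27, 35, 125 and 52 in EV and 63, 37, 13 and 24 in KD. The count of 0 allowed a level of up to 0.541 CPM in that library. The log2 fold change of LACC1 in KD against EV was -0.49 (SE 0.87, 95% interval -2.32 to 1.33) in Th0 and -0.66 (SE 0.96, 95% interval -2.69 to 1.36) in iTreg, with an adjusted p of 1 in both (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). It was lower in KD in 3 of 5 donor pairs in Th0 and in 2 of 4 in iTreg. A two-sided exact permutation test of log2 CPM gave p = 0.341 in Th0 over 252 assignments and p = 0.429 in iTreg over 70, where the smallest p possible was 0.00794 and 0.0286. A lower level of LACC1 RNA in the libraries labelled KD was not detectable at this depth and spread. The Th0 log2 fold change was 0.02 without Th0 EV replicate 3 and -0.95 without Th0 KD replicate 4. The iTreg value was -0.11 without iTreg EV replicate 3 and -1.02 without iTreg KD replicate 1.

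**Figure D2:**
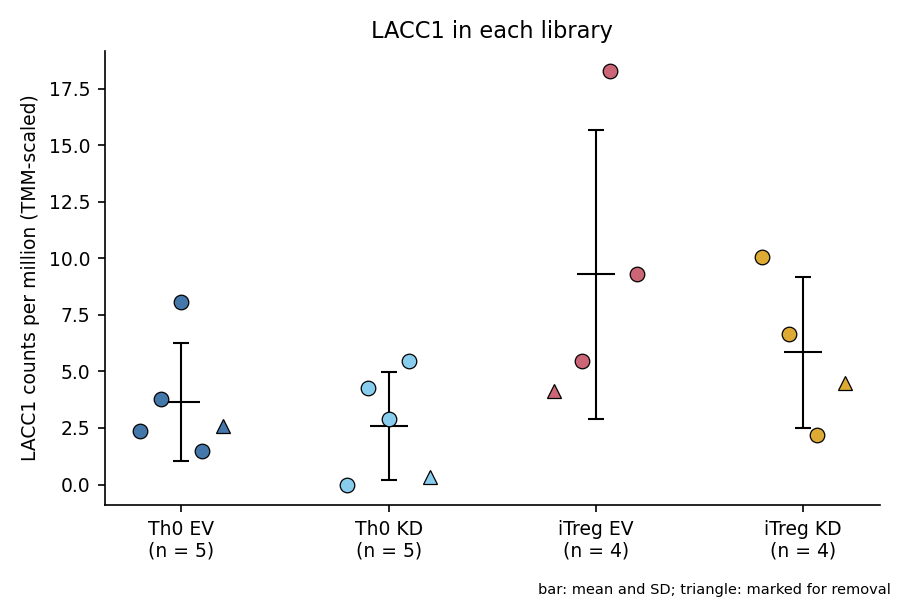
LACC1 level in CPM in each library, by group. Points are libraries, triangles the 4 marked libraries and bars the group mean ± SD, which overlap between EV and KD in both cell types.

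The comparison of iTreg EV with Th0 EV asked what the iTreg condition changed in cells without the hairpin. CTSL, encoding the lysosomal protease cathepsin L, rose from 13.99 ± 6.01 CPM (SD, n = 5) in Th0 EV to 1299 ± 548 CPM (n = 4) in iTreg EV, a log2 fold change of 6.54 (SE 0.50, adjusted p = 2.57e-06, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). GPR157, an orphan G protein-coupled receptor, rose from 1.41 ± 1.94 to 164 ± 59.0 CPM (adjusted p = 1.31e-04). INAVA, CYS1, DHRS2 and MMP2, the last of which encodes matrix metalloproteinase-2, had 0 counts in Th0 EV and means of 37.2 ± 21.6, 37.0 ± 25.7, 36.2 ± 25.5 and 31.8 ± 35.2 CPM in iTreg EV. By counts pooled over each group, without TMM scaling, they were at least 417-, 402-, 411- and 328-fold higher against a floor of 3 counts over the Th0 EV group, with adjusted p of 5.33e-04, 0.00449, 0.00382 and 0.0336. For MMP2, iTreg EV replicate 4 held 460 of the 754 pooled counts, and for DHRS2 replicate 3 held 491 of 945, so these bounds lean on 1 library. PTK2 (log2 fold change 6.77, adjusted p = 0.00842), which encodes focal adhesion kinase, PLEK2 (6.70, 0.0144), CHRNA6 (7.92, 0.0308) and GLT1D1 (5.99, 0.0308) rose from under 1 CPM. Most of their few Th0 EV counts lay in 1 library, replicate 4 for PTK2 (8 of 11) and PLEK2 (8 of 9). For CHRNA6 (3 of 4) and GLT1D1 (13 of 16) that was the marked replicate 5, so the size of these folds is uncertain. For CHRNA6 the marked library iTreg EV replicate 1 held 851 counts against 21, 33 and 29 in replicates 2 to 4, and without it the log2 fold change was 4.91 (adjusted p = 0.149). Among genes that fell, the prostaglandin E2 receptor gene PTGER2 went from 718 ± 215 to 65.4 ± 25.6 CPM (log2 fold change -3.46, SE 0.47, adjusted p = 9.10e-04). TRIB2, a pseudokinase gene, fell from 195 ± 44.7 to 14.4 ± 5.25 CPM (adjusted p = 0.00119) and TSPAN18 from 75.9 ± 45.2 to 2.17 ± 1.62 CPM (adjusted p = 0.00495). ROPN1L, RAMP1, CCNI2, HKDC1, MAP3K5 and TBXA2R fell as well, with log2 fold changes of -4.84, -4.63, -4.58, -4.01, -3.40 and -3.19. Each of these named genes moved the same way in 4 of 4 donor pairs, which the naming rule required, so it lends them no further support.

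Of 12629 genes tested, 151 passed, 101 higher and 50 lower in iTreg EV, and 1052 had an unadjusted p under 0.05. The count was 292 (186 higher, 106 lower) with the donor as a block, 435 with DESeq2, 451 without the 4 marked libraries and 783 (431 higher, 352 lower) with the removal mark as a covariate, and all 151 genes kept their sign with the block, without the marked libraries and with the covariate. In simulated counts of this comparison DESeq2 made 19 false calls and edgeR 2, so the 435 is less certain. The edgeR count fell to 79 without iTreg EV replicate 2 and to 90 and 94 without iTreg EV replicates 4 and 3. It was 92, 97 and 99 without Th0 EV replicates 2, 4 and 3. Of the 30 named genes called, 16 kept their call in each of the 9 fits that left out 1 library, and 14 lost it in 1 to 9 of them with an adjusted p of at most 0.149 and no change of sign. OAS3 lost it in 9 of these fits, CCNI2 in 8, and AHR, CD83, GLT1D1, MMP2 and TBXA2R in 7. ITGAE, RAMP1 and ROPN1L lost it in 6, CHRNA6 and ISG15 in 5, HKDC1 in 1 (without iTreg EV replicate 2, adjusted p = 0.0563) and MAP3K5 in 1 (without iTreg EV replicate 4, adjusted p = 0.0585). Of the 30, 9 share exon sequence with another annotated gene (AHR, CCNI2, HKDC1, ISG15, ITGAE, MMP2, PMEPA1, ROPN1L and TSPAN18), 8 of them with a gene on the other strand. The library kit does not mark strand, so reads in exons shared across strands could not be assigned by strand. How reads in shared exons were counted was not given in the sources used here, so the counts of these 9 are uncertain.

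Genes of the TGF-β response list rose in iTreg EV. Of 18 measured members, 6 rose, 1 fell and 11 did not pass, and adjusted over the list alone 7 rose and 1 fell. SKIL, a feedback inhibitor of SMAD signalling, rose from 17.3 ± 7.33 CPM (SD, n = 5) to 184 ± 135 CPM (n = 4; log2 fold change 3.41, SE 0.50, adjusted p = 0.00199, edgeR). PMEPA1, another SMAD-induced inhibitor, rose from 0.643 ± 0.700 to 39.5 ± 44.3 CPM (log2 fold change 5.93, adjusted p = 0.0158), with 688, 130, 146 and 61 counts in iTreg EV replicates 1 to 4. Without the marked replicate 1, SKIL and PMEPA1 had log2 fold changes of 2.77 and 4.76. ITGAE, encoding the integrin CD103, rose from 15.6 ± 17.3 to 220 ± 144 CPM (adjusted p = 0.0265). LDLRAD4 and SMURF2 had log2 fold changes of 2.51 and 2.09 (adjusted p = 9.30e-05 and 0.00201), and TGFBI rose from 0 counts to 6.40 ± 4.75 CPM, at least 72.2-fold higher by the same pooled counts. Of the 166 pooled TGFBI counts, 86 were in the marked iTreg EV replicate 1. SMAD3, the TGF-β signal transducer, fell from 72.3 ± 22.2 to 15.0 ± 5.87 CPM (log2 fold change -2.27, adjusted p = 0.00597). The list as a whole had a median log2 fold change of 0.77, also with TGFBI at its bound, and passed camera (adjusted p = 1.99e-05). Its adjusted p = 0.00388 with an estimated correlation, and adjusted p = 0.105 with an estimated correlation and the donor block.

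Interferon-stimulated genes were higher in iTreg EV. ISG15, a ubiquitin-like antiviral protein, rose from 447 ± 272 CPM (SD, n = 5) to 2008 ± 593 CPM (n = 4; log2 fold change 2.17, SE 0.48, adjusted p = 0.0308, edgeR). OAS3, a sensor of double-stranded RNA, rose from 31.7 ± 14.3 to 105 ± 16.0 CPM (log2 fold change 1.73, adjusted p = 0.0460). The other 28 of the 30 members did not pass, among them the antiviral GTPase gene MX1 at 218 ± 160 and 916 ± 321 CPM (adjusted p = 0.0603). Adjusted over the list alone, 11 rose. The log2 fold change was positive in 28 of 30 members, with a median of 1.71 and a camera adjusted p of 1.01e-13, and without iTreg EV replicate 1 a median of 1.11 (adjusted p = 2.08e-07). This call was lost with an adjusted p = 0.116 with an estimated correlation. NF-κB targets passed camera as well (16 members, 14 positive, median log2 fold change 0.68, adjusted p = 0.00498). That second call was lost with an adjusted p = 0.148 with an estimated correlation. CD83, a costimulatory surface protein, was the member that rose, from 17.5 ± 5.75 to 72.9 ± 27.4 CPM (adjusted p = 0.0460; 0.0724 with the donor block, edgeR), and adjusted over the list alone 2 rose.

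None of the 15 measured members of the regulatory T cell list passed, and adjusted over the list alone 1 rose. FOXP3 was at 8.15 ± 5.67 CPM (SD, n = 5) in Th0 EV and 60.7 ± 46.0 CPM (n = 4) in iTreg EV, a log2 fold change of 2.90 (SE 0.80, adjusted p = 0.113, edgeR) that was positive in 4 of 4 donor pairs. With the removal mark as a covariate FOXP3 passed, at 3.02 (adjusted p = 0.0115). IL2RA was at 179 ± 315 and 242 ± 388 CPM (823 CPM on average in the marked libraries). The chemokine receptor gene CCR4 was at 13.0 ± 21.9 and 139 ± 217 CPM (adjusted p = 0.356; 0.0136 with the donor block). In the block fit the marked iTreg EV replicate 1 stands against the unmarked Th0 EV replicate 1, so calls there cannot be fully told apart from the mark. The list had a median log2 fold change of 0.48 and a camera adjusted p of 0.113, which became 0.0284 with the donor block and 0.0229 with the mark as a covariate. In those 2 fits it had an adjusted p = 0.507 and 0.177 with an estimated correlation.

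Among lists of other T cell states, single members passed while no list did in the model without the donor block or the removal mark. AHR, the aryl hydrocarbon receptor, rose from 22.6 ± 7.32 CPM (SD, n = 5) to 77.7 ± 21.8 CPM (n = 4; log2 fold change 1.78, adjusted p = 0.0308, edgeR) as 1 of 7 members of the Th17 list (median 0.49, camera adjusted p = 0.0616). TOX2, a nuclear factor of chronically stimulated T cells, rose from 6.88 ± 2.09 to 154 ± 72.4 CPM (log2 fold change 4.48, adjusted p = 0.00315) as 1 of 14 members of the coinhibitory list (median 0.83, adjusted p = 0.224). With the donor block, where the mark is partly mixed with cell type, that list passed (adjusted p = 0.0442), a call lost with an adjusted p = 0.507 with an estimated correlation. DUSP4, a phosphatase induced by T cell activation, rose from 84.9 ± 25.3 to 372 ± 79.9 CPM (log2 fold change 2.13, adjusted p = 5.33e-04) as 1 of 17 members of the early activation list (median 0.38, adjusted p = 0.792). KLF2, a factor of quiescent and recirculating T cells, fell from 236 ± 110 to 21.7 ± 7.55 CPM (log2 fold change -3.44, SE 0.46, adjusted p = 7.35e-04) as 1 of 16 members of the naive and memory list. The median of 0.35 and mean of 0.05 of that list were positive while its test pointed down (adjusted p = 0.990). Adjusted over the list alone, 1 Th17 gene rose, 2 coinhibitory genes rose and 1 fell, 3 early activation genes rose and 2 fell, and 2 naive and memory genes rose and 1 fell. No member of the Th1 (12 measured, median 0.14, adjusted p = 0.792), Th2 (7 measured, median 0.63, adjusted p = 0.792) or cytotoxic list (10 measured, median -2.21, adjusted p = 0.0568) passed. The Th2 factor GATA3 had a log2 fold change of -0.03 and the pore-forming protein gene PRF1 one of -0.44. Adjusted over the list alone, 1 Th1 gene rose and 1 fell, and 1 Th2 gene rose. Between marked and unmarked libraries the list medians differed by 3.31 log2 units for cytotoxic and 3.06 for coinhibitory. They differed by 0.96 for Th1, 1.53 for Th2, 0.64 for naive and memory, -0.65 for Th17 and -0.67 for early activation. Where members were measured at lower levels in the unmarked libraries, a lack of calls does not show a lack of change.

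**Figure D3:**
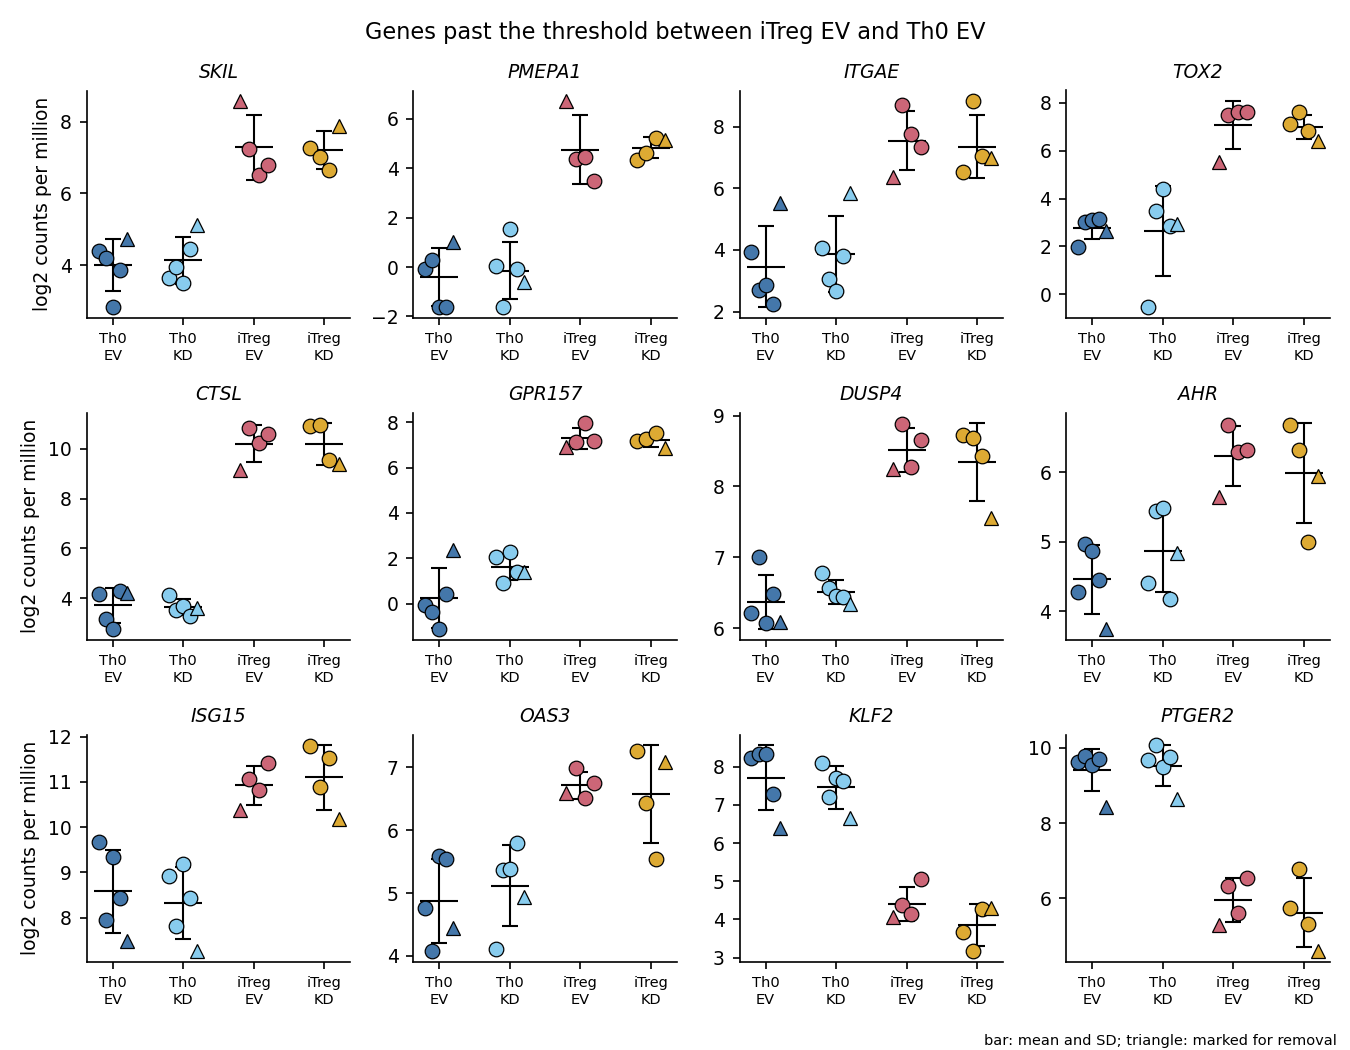
Level in log2 CPM of 12 genes in each library of the 4 groups, with the group mean ± SD. Triangles are the 4 marked libraries; SKIL, PMEPA1, ITGAE, TOX2, CTSL, GPR157, DUSP4, AHR, ISG15 and OAS3 rose and KLF2 and PTGER2 fell in iTreg EV against Th0 EV.

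Of the members of the metabolic, stress and cell cycle lists, only CTSL passed between iTreg EV and Th0 EV, as 1 of 30 members of the autophagy and lysosome list (median log2 fold change 0.24, camera adjusted p = 0.0670; 3 rose when adjusted over the list alone). The proliferation list had a median of -0.38 (adjusted p = 0.0695), with -0.32 for the proliferation marker MKI67. The glycolysis list had a median of -0.43 (adjusted p = 0.113), with -0.50 for lactate dehydrogenase A (LDHA). The mitochondrially encoded genes had a median of -0.43 (adjusted p = 0.0695), with -1.08 for MT-CYB. The ribosomal protein genes, which took more of the counts in the marked libraries, had a median of -0.42 (adjusted p = 0.0568). The purine list, the pathway in which LACC1 acts, had a median of -0.24 (adjusted p = 0.376). The tricarboxylic acid cycle, fatty acid oxidation and sterol and fatty acid synthesis lists had medians of 0.03, 0.24 and -0.07 (adjusted p = 0.860, 0.556 and 0.792). The amino acid response list of ATF4 had a median of 0.06 and the unfolded protein response list one of -0.17 (adjusted p = 0.931 and 0.415). XBP1, a transcription factor of the latter, was at 1419.5 ± 555 CPM (SD, n = 5) and 689 ± 255 CPM (n = 4; adjusted p = 0.414, edgeR; 0.0291 with the donor block). For 4 further lists the median and the mean differed in sign. These were oxidative phosphorylation (-0.02 and 0.04, test down, adjusted p = 0.674) and arginine and polyamine metabolism (-0.05 and 0.17, down, 0.990). The others were NRF2 antioxidant (-0.14 and 0.13, down, 0.792) and p53 targets (-0.10 and 0.07, up, 0.792). Oxidative phosphorylation genes were a median of 2.76 log2 units higher in the marked libraries (44 of 71 higher, 20 lower, edgeR), which limits that test.

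Lists of other cell types and of RNA quality did not pass in this comparison. In the marked libraries, CD4 T cell identity genes were a median of 3.13 log2 units higher (11 of 16 higher, 3 lower, edgeR), which limits their test. CD4 T cell identity genes had a median log2 fold change of 0.02 (16 measured, camera adjusted p = 0.950), B cell markers -0.82 (5 measured, adjusted p = 0.376; 1 fell when adjusted over the list alone) and monocyte and dendritic cell markers 1.14 (3 measured, adjusted p = 0.415; 1 rose when adjusted over the list alone). Only 2 NK cell markers (median -0.68) and 2 CD8 T cell markers (median 1.13) were measured, and 0 erythroid and platelet markers, too few for a test of the list. Histone genes had a median of -0.50 (adjusted p = 0.0731) and nuclear and immediate stress RNAs one of -0.14 (adjusted p = 0.792). With the removal mark as a covariate, 12 lists passed, 6 up and 6 down. Among them were the ribosomal protein list (18 of 73 genes fell, adjusted p = 6.01e-11) and the mitochondrially encoded list (down, 0.00248). Others were the cytotoxic list (down, 0.00231, with CST7, GZMA, GZMB and NKG7 lower) and the proliferation list (down, 0.00667). In the same order these had an adjusted p = 0.204, 0.654, 0.0609 and 0.670 with an estimated correlation.

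**Figure D4:**
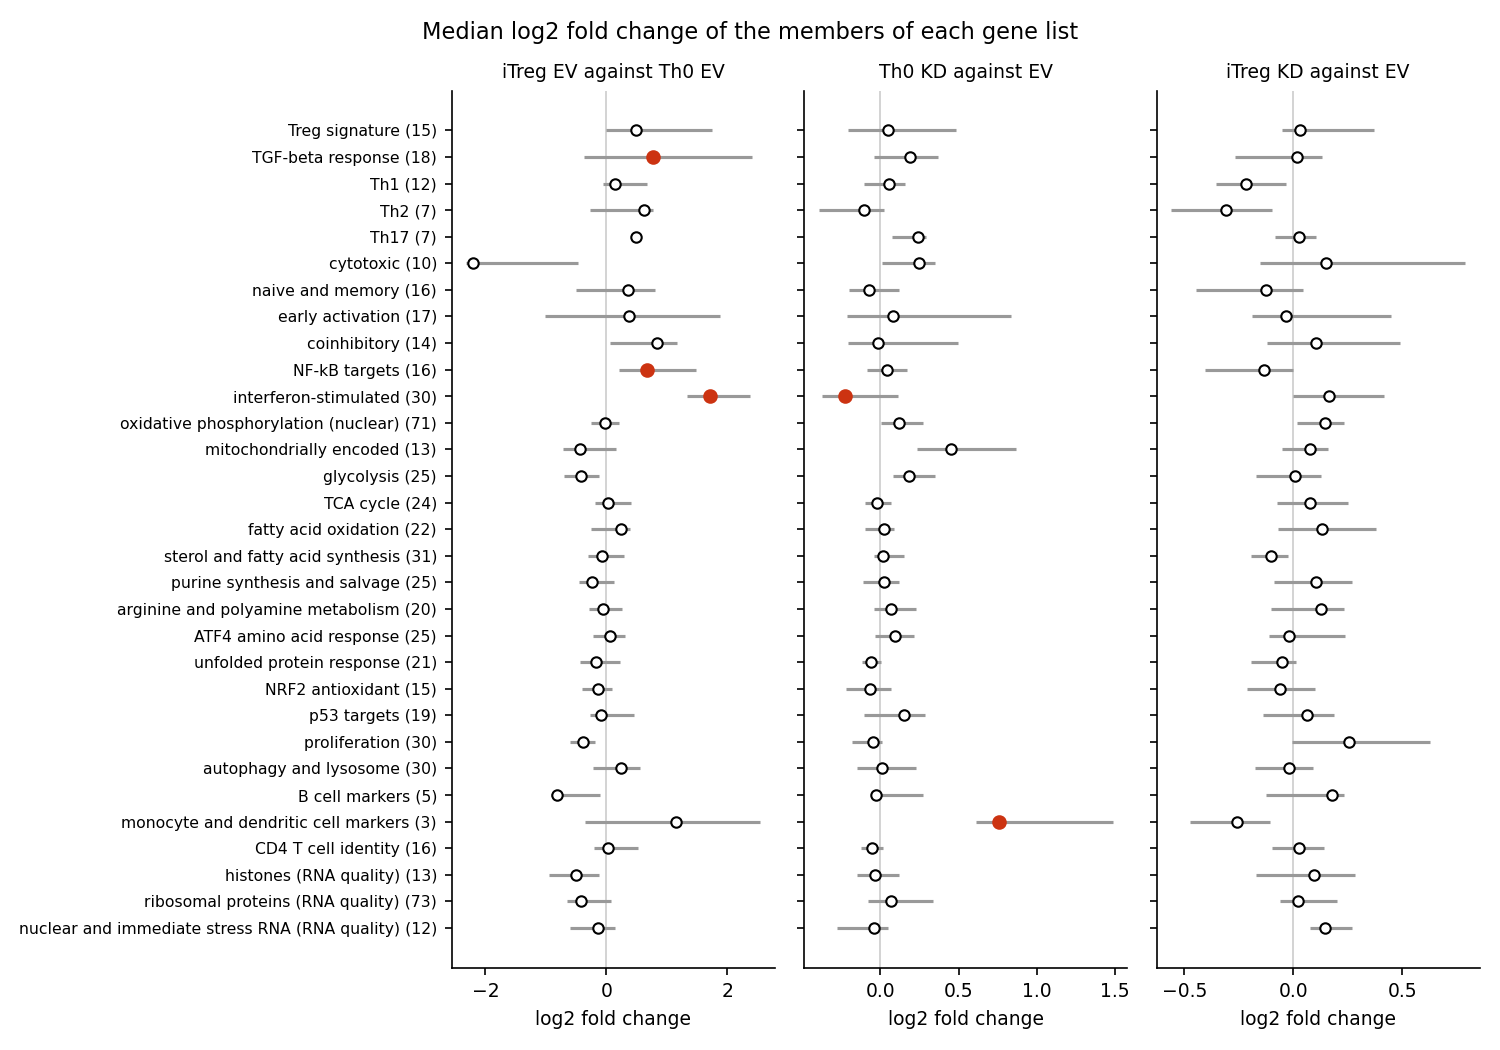
Median log2 fold change of each gene list with its quartile range, for iTreg EV against Th0 EV and for KD against EV in both cell types; the number of members tested is in brackets. Filled red points are lists with a camera adjusted p under 0.05, of which there were 3 for iTreg EV against Th0 EV, 2 for Th0 KD and 0 for iTreg KD.

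The KD libraries gave a separate set of samples for the same contrast. In iTreg KD against Th0 KD, 140 genes passed edgeR's quasi-likelihood test, 77 higher and 63 lower. The count was 335 (187 higher, 148 lower) with the donor block, 479 without the marked libraries and 846 (430 higher, 416 lower) with the mark as a covariate. Of the 151 genes called between the EV groups, 151 had the same sign and 96 were also called, where independent lists of these sizes would share 1.67. Across the 12629 genes, which are not independent replicates, the log2 fold changes of the 2 contrasts had a Pearson r of 0.727. The 2 contrasts shared donors but no library. They came from 1 fit, with the same filter and the same estimate of the spread for each gene. The 1.67 is therefore not a fair measure of chance here.

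The comparison of KD with EV in Th0 asked what the hairpin against LACC1 changed in activated, non-polarised cells. Among interferon-stimulated genes, ISG15 was at 358 ± 177 CPM (SD, n = 5) in KD and 447 ± 272 CPM (n = 5) in EV (log2 fold change -0.32, SE 0.44). MX1 was at 151 ± 112 and 218 ± 160 CPM. MAP1LC3B, encoding the autophagosome protein LC3B, was at 342 ± 41.7 CPM in KD and 250 ± 37.8 CPM in EV, higher in 5 of 5 donor pairs (log2 fold change 0.45, SE 0.30). The protease genes CTSH and GZMM were at 393 ± 108 and 327 ± 100 CPM and at 86.7 ± 43.7 and 69.1 ± 34.9 CPM. MYC, a driver of growth in activated T cells, was lower in 5 of 5 (232 ± 91.9 and 279 ± 108 CPM, log2 fold change -0.27). Among all genes tested many move the same way in every pair by chance, so these pair counts lend no support. IL2RA, GATA3, LDHA and MKI67 had log2 fold changes of 0.08, 0.04, 0.04 and -0.07. All of these genes had an adjusted p of 1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment).

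With edgeR, 0 of 12629 genes passed in Th0, 68 had an unadjusted p under 0.05, and DESeq2 called 0 (119 unadjusted). With the donor block DESeq2 called CYS1, MMP9 and MID2 (adjusted p = 0.0491, 2.05e-16 and 0.0111), MMP9 with 111 counts in all. In that model edgeR called 0. In simulated counts of this comparison, without a donor effect, DESeq2 made 34 false calls and edgeR 0. Without the marked libraries edgeR again called 0 (246 unadjusted). Of the 31 lists tested, 2 passed camera and 8 had a median, mean and test that differed in sign, none of them called. Interferon-stimulated genes were lower in KD (30 members, 11 positive, median log2 fold change -0.23, adjusted p = 0.0286), a call lost with an adjusted p = 0.809 with an estimated correlation. The 3 measured monocyte and dendritic cell markers were higher in KD (median 0.76, adjusted p = 0.0286), a call lost with an adjusted p = 0.222 with an estimated correlation. They were CD14 at 3.74 ± 1.26 and 2.21 ± 1.64 CPM, ITGAX at 8.47 ± 8.00 and 6.16 ± 5.53 CPM and CST3 at 0.966 ± 1.27 and 0.199 ± 0.276 CPM. The interferon call was lost in 6 of 10 fits that left out 1 library (Th0 EV replicates 1, 3 and 5, Th0 KD replicates 1, 2 and 4). The marker call was lost in 7 (Th0 EV replicates 2, 3, 4 and 5, Th0 KD replicates 2, 4 and 5). Adjusted p reached 0.562 and 0.550 without Th0 EV replicate 3. Without the low-count filter or with a stricter one 0 lists passed. With the removal mark as a covariate the interferon list and the proliferation list passed as lower in KD (adjusted p = 0.00317 and 0.0227), and the marker list did not (0.0969). Both of these calls were lost with an adjusted p = 0.723 and 0.799 with an estimated correlation. The other lists had medians of at most 0.45 in size, which was that of the mitochondrially encoded list (mean 0.61, test down, adjusted p = 0.329). Without the marked libraries its median turned to -0.50 and it passed as lower in KD (adjusted p = 1.03e-05), a call lost with an adjusted p = 0.589 with an estimated correlation.

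In iTreg the same question was asked of cells under the polarising condition. FOXP3 was at 53.96 ± 19.9 CPM (SD, n = 4) in KD and 60.7 ± 46.0 CPM (n = 4) in EV (log2 fold change -0.17), and IL2RA had a log2 fold change of 0.12. The TGF-β response genes ITGAE and SKIL had log2 fold changes of -0.13 and -0.24, and GATA3 one of -0.31. ISG15 was at 2400 ± 1070 CPM in KD and 2008 ± 593 CPM in EV and MX1 at 1055 ± 245 and 916 ± 321 CPM. The lysosomal protease genes CTSL and CTSB both had a log2 fold change of 0.04, the replication licensing gene MCM4 one of -0.36, LDHA one of -0.11 and the NF-κB inhibitor gene NFKBIA one of -0.13. CD8B, a marker of CD8 T cells, was at 10.4 ± 8.52 CPM in KD and 19.6 ± 12.8 CPM in EV. It was lower in 4 of 4 donor pairs (log2 fold change -0.91), which many of the tested genes reach by chance. All of these genes had an adjusted p of 1 (edgeR).

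With edgeR, 0 of 12629 genes passed in iTreg, 76 had an unadjusted p under 0.05, and DESeq2 called 0 (117 unadjusted). Without the marked libraries edgeR again called 0 (288 unadjusted). No list passed camera, where the lowest adjusted p was 0.172, shared by NF-κB targets (median log2 fold change -0.13), proliferation (0.25) and the monocyte and dendritic cell markers (-0.26). For 9 lists, none of them called, the median, mean and test differed in sign. In the B cell list 1 gene was higher when adjusted over the list alone. With the removal mark as a covariate, proliferation and nuclear-encoded oxidative phosphorylation genes passed as higher in KD (adjusted p = 0.0357 for each), and both calls were lost with an adjusted p = 0.857 with an estimated correlation.

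The difference of the KD effect between iTreg and Th0 was tested in the same fit. ISG15 was lower in KD by the means in Th0 and higher in iTreg, but no single gene passed for the difference (0 of 12629 with edgeR, 76 with an unadjusted p under 0.05, DESeq2 0 with 114 unadjusted). For lists, interferon-stimulated genes differed by a median log2 of 0.35 (iTreg minus Th0, camera adjusted p = 0.0112), a call lost with an adjusted p = 0.747 with an estimated correlation. Proliferation genes differed by 0.41 (adjusted p = 0.0112), lost with an adjusted p = 0.726 with an estimated correlation. The monocyte and dendritic cell markers differed by -1.01 (adjusted p = 0.00459), lost with an adjusted p = 0.0566 with an estimated correlation. Across genes, which are not independent replicates, the KD effects in Th0 and iTreg had a Pearson r of -0.013 (two-sided exact permutation p = 0.857 over 70 assignments of the iTreg labels).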

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

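Of the tests in this part, those of other cell types, of LACC1, of 2-fold changes, of 4-fold changes with the mark as a covariate and of leaving out the marked libraries were chosen only after the result was seen.

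The 4 libraries with a removal mark, 1 per group, stood apart from the libraries of their own groups. On the first principal component the scores were 167 for Th0 EV replicate 5, 176 for Th0 KD replicate 5 and 176 for iTreg KD replicate 4, each far from the rest of its group. Ribosomal protein genes took 2.88% of counts in Th0 EV replicate 5, 3.08% in Th0 KD replicate 5, 2.18% in iTreg EV replicate 1 and 2.07% in iTreg KD replicate 4. Mitochondrially encoded genes took 7.70% in Th0 EV replicate 5 and 5.69% in iTreg KD replicate 4, and ACTB took 3.41% in iTreg EV replicate 1. Of 105 named genes, 28 in Th0 EV, 24 in Th0 KD, 18 in iTreg EV and 9 in iTreg KD had a library far from the others, which was the marked one in 21, 18, 18 and 8 cases. Of 33 list means, 11, 9, 3 and 12 had one, the marked library in 11, 8, 2 and 11 cases, where chance gives about 1 in 20 groups.

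For the distance of the marked libraries, 3 technical explanations were weighed. Gene length explained 1.12% of the variance across genes of the marked minus unmarked difference, which argues against a length bias. Markers of another cell type reached at most a mean of 91.3 CPM in the unmarked libraries, for the NK cell list and from CD7 at 268 CPM, which T cells also express. That decides nothing where CD3E and CD4 themselves are at 13.7 and 40.8 CPM, so such cells stay open, although naive CD4+ T cells were isolated. The mean GC content of the transcript explained 17.6% of the variance, less than a whole cause would need and more than none. GC content thus remains a candidate explanation that is left open, and GC-rich stretches are taken up under the other observations. The marked iTreg libraries of donors 1 and 4 both scored 176 on the first principal component. The unmarked iTreg libraries of these donors, with the other vector, scored -55.3 and -27.7. If the donor numbers of the labels hold, this argues against a donor trait as the cause in these 2 donors. The pairing check gave -0.601 and -0.367 for these pairs, so it does not bear out their donor numbers. Both libraries of donor 5 were marked, and the design holds no group that would test other biological explanations.

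The absence of called genes between the libraries labelled KD and EV was the next pattern. Leaving out the marked libraries gave 0 calls in both cell types with edgeR (246 and 288 genes at an unadjusted p under 0.05), which argues against their spread as the whole cause. At the spread of all 18 libraries 25% of simulated 4-fold changes in Th0 and 11% in iTreg were called, so real ones may have gone uncalled there. With the mark as a covariate these shares were 95% and 79% for genes with a simulated mean of at least 50 counts. With 0 calls in that fit too, this argues against too few libraries for changes of that size in such genes. It holds only if about as many genes changed as in the simulation (200). Fewer changed genes were not simulated, and 4-fold changes in a few genes may have gone uncalled. Lower genes, LACC1 among them, were not covered by the simulation, and 4-fold changes there may have gone uncalled. For 2-fold changes the share was 33% at most, so these may have gone uncalled as well. The 95% interval of the LACC1 log2 fold change included 0 in both cell types with that covariate (upper bound 0.912 in Th0), so a knockdown too small to measure in LACC1 RNA may also account for the pattern, and a lack of effect of LACC1 on the cells' RNA, the biological explanation, stays open.

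Interferon-stimulated genes were higher in iTreg EV than in Th0 EV. The list median kept 97.9% of its value with the trend on mean transcript GC content removed, which argues against mean GC content as the whole cause. That fit does not cover GC-rich stretches of transcripts. The highest GC share of a 75-nt window explained 52.1% of the variance of the marked minus unmarked difference, against 15.0% for mean GC content. The list median kept 80.2% without the marked libraries and at least 64.8% with any 1 library left out (the lowest without iTreg EV replicate 1). These values argue against the marked libraries or any 1 library as the whole cause. The list itself was a median of 2.58 log2 units higher in the marked libraries (19 of 30 members higher, 6 lower, edgeR). The fit without them therefore rests on libraries in which most members were measured at lower levels. The call was lost with an estimated correlation (adjusted p = 0.116), so members moving together through some other difference between cultures may account for it, and a response to the iTreg condition, which the design names, is a hypothesis that stays open as untested by an independent experiment. For the comparison as a whole, 1 of 100 drawn splits of the 9 libraries, the real one, gave as many as 151 calls and the highest of the others gave 4. With 100 of 126 possible splits drawn, the share could not fall below 1%, and most of these splits ignored the donor pairs. That highest split had both marked libraries on the same side. Among the 15 drawn splits that part as many donor pairs the highest was also 4, but so few splits cannot reach a share under 0.05. Chance is therefore made unlikely and is not excluded.

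For KD against EV, 100 of 100 splits of the libraries in Th0 and 35 of 35 in iTreg had as many calls as the real 0, with 0 the highest of the others. A real count of 0 is reached by any split, so these splits say nothing of chance. For the difference of the KD effect between iTreg and Th0, the interferon-stimulated list had a camera adjusted p of 0.0112, the proliferation list 0.0112 and the monocyte and dendritic cell list 0.00459 in a test of the difference itself, and 0.747, 0.726 and 0.0566 with an estimated correlation. For single genes, 100 of 100 splits gave at least the real count of 0, which again says nothing of chance, and the highest of the other splits called 4265 genes with all 4 marked libraries on the same side, which points to a structure of the samples. Among the 32 splits that balanced the marked libraries the highest count was 0. In an untested count, 10 of 12629 genes moved one way in every Th0 pair and the other way in every iTreg pair, and 0 of the 105 named genes did. The 10 genes are fewer than the 0.391% that independent pairs would give. The marked library was EV in iTreg pair 1 and KD in iTreg pair 4, so that rate is not a fair measure of chance here.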

How the results depend on the processing

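Fits without the marked libraries, with the mark as a covariate and with the GC trend removed were chosen only after the data were seen. For iTreg EV against Th0 EV the 151 calls became 435 with DESeq2, 292 with the replicate block for the donor, 451 without the 4 marked libraries, 783 with the mark as a covariate, 843 with mark and block and 557 with the block and no marked libraries, and 79 to 158 with 1 library left out (79 without iTreg EV replicate 2, 158 without Th0 EV replicate 5). The fit with the covariate had a biological coefficient of variation of 0.452 against 0.854, and for the other changes the cause was not tested. With the block, 292 became 955 with DESeq2 and 53 with only the groups compared. The blocked edgeR count was 72, 102, 124, 188 and 266 without donor replicates 2, 3, 4, 5 and 1. In simulated counts of this comparison, without a donor effect, DESeq2 made 19 false calls and edgeR 2. All 151 genes kept their sign in the block, mark and GC fits, and 145, 149, 151 and 117 of them were called with the block, without the marked libraries, with the covariate and with the GC trend removed.

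KD counts of 0 held in 24 of 24 alternatives to the unblocked edgeR model in Th0 and in 21 of 22 in iTreg, where log2(TPM + 0.1) called 1 gene, MSX2P1 (log2 fold change -4.83, adjusted p = 0.0328). With the block, DESeq2 called 3 in Th0 (CYS1, adjusted p = 0.0491; MMP9, 2.05e-16, with 111 counts in all; MID2, 0.0111), edgeR 0 with any donor left out, and in iTreg 0 to 1, which was CD3G without replicate 1 (adjusted p = 0.0314), a gene 3.63 log2 units higher in the marked libraries. These genes were named after their values were seen, and the cause was not tested. In simulated counts of KD in Th0, without a donor effect, DESeq2 made 34 false calls and edgeR 0. The difference of the KD effects stayed at 0 in all 32 alternatives, 0 to 0 with 1 library left out. The LACC1 log2 fold change stayed negative except in Th0 without Th0 EV replicate 3 (0.0210, lowest -0.95), and in iTreg ran from -1.02 to -0.11. Among the named genes the block ended the call of CD83 and gave one to XBP1 and CCR4. The correlation of KD effects ran from -0.0932 without Th0 KD replicate 5 to 0.0869 without Th0 EV replicate 5 (exact p from 0.400 to 0.914), and a correlation over called genes could not be computed with 0 of them.

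For the lists, 3 passed between iTreg EV and Th0 EV, which became 5 without the low-count filter, 7 with the stricter one, 5 with the replicate block, and 6 each on log2(TPM + 1), with only the groups compared and with the GC trend removed. The count was 9 without the marked libraries, 12 with the covariate, 11 with the covariate and the block, 10 with the block and no marked libraries, 1 with an estimated correlation and 0 with that and the block, and 3 (without Th0 EV replicate 5) to 10 (without Th0 EV replicate 1) with 1 library left out. In Th0 KD, 2 became 0 with either filter change, 1 with only the groups compared, 4 without the marked libraries (interferon-stimulated, mitochondrially encoded, which turned down, proliferation and TGF-β response, with adjusted p of 0.619, 0.589, 0.828 and 0.439 at an estimated correlation and the monocyte and dendritic cell list lost), 5 with the block besides, 0 with an estimated correlation with or without the block, and 0 (without Th0 EV replicate 3) to 5 (without Th0 KD replicate 3). In iTreg KD, 0 became 2 with the covariate, 2 with covariate and block, 2 with the block and no marked libraries, and 0 to 4 (without iTreg EV replicate 1). The 2 calls with the covariate were lost with an estimated correlation, which was not run for the others of these iTreg KD fits. Apart from the filters and left-out libraries, which change what enters the test, the cause was not tested.

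Of the 30 named genes called between iTreg EV and Th0 EV, 15 kept their call in every setting. Of 690 values, 576 kept it, 114 did not and 0 changed sign. Of 1172 values of the 51 named genes not called, 31 passed, 29 of them in the fits added for the marked libraries. Depth limits low genes such as LACC1, whose highest count was 125.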

Other observations

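The genes in the first paragraph and the test of GC-rich windows were chosen only after the values were seen.

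Outside the lists, further genes passed between iTreg EV and Th0 EV in both directions. KLF3, a relative of KLF2, fell from 114 ± 22.7 CPM (SD, n = 5) to 16.9 ± 4.88 CPM (n = 4; log2 fold change -2.75, adjusted p = 9.30e-05, edgeR). ID2, an inhibitor of helix-loop-helix factors, fell from 105 ± 30.7 to 27.7 ± 11.3 CPM (adjusted p = 0.0227), and ITGB7, an integrin chain of gut homing, from 771 ± 166 to 260 ± 89.4 CPM (adjusted p = 0.0482). HBEGF, an EGF receptor ligand, fell from 88.1 ± 20.2 to 12.1 ± 4.54 CPM (adjusted p = 5.33e-04), and HES1, a Notch target, by a log2 fold change of -2.72 (adjusted p = 0.0192). Of the phosphatase genes, DUSP1 and DUSP5 fell (-2.02 and -1.64, adjusted p = 0.0435 and 0.0310) whereas DUSP4 rose. RGS16, a regulator of G protein signalling, rose from 17.96 ± 16.9 to 496 ± 255 CPM (adjusted p = 0.00315), IL4I1, a secreted amino acid oxidase, from 5.69 ± 4.74 to 125 ± 46.9 CPM (adjusted p = 0.00876), and TNFSF13B, encoding the B cell factor BAFF, from 19.0 ± 10.9 to 193 ± 94.0 CPM (adjusted p = 9.78e-04). EIF2AK2, the interferon-inducible kinase PKR, rose from 317 ± 136 to 1000.2 ± 334 CPM (adjusted p = 0.0227).

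A hypothesis on the marked libraries was that the 14 unmarked libraries hold reads mainly from GC-rich stretches of transcripts, so that transcripts without such a stretch are depleted from them. Of 12629 genes, 4311 were higher and 3936 lower in the marked libraries (adjusted p under 0.05, edgeR). Of 6818 genes at 20 CPM or more in the marked libraries, a filter that favours genes higher there, 2622 (38.5%) were over 2-fold higher and 785 over 16-fold. In 3409 genes on which the window was not chosen, the highest GC share of any 75-nt window explained 52.1% of the variance of the marked minus unmarked log2 difference, against 15.0% for mean GC content. The median difference was 4.51 for genes whose richest window was under 60% GC (68 genes), 1.61 at 70% to 75% (669 genes) and -0.84 at 80% or more (1403 genes). At a mean GC content of 45% to 50%, it was 3.86 for 126 genes with no window reaching 70% and -0.63 for 343 genes with one of 75% or more. These values are consistent with the hypothesis, which was found and tested on the same libraries and says nothing of the step at which such reads would have been lost. IL2RA and CD3E, whose richest windows are 65.3% and 68.0% GC, were 4.35 and 4.08 log2 units higher in the marked libraries, while KLF2 and LACC1, with windows of 90.7% and 78.7%, differed by -0.63 and -1.16. GAPDH, with a window of 77.3%, went against the trend and was 3.42 log2 units higher in the marked libraries.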
